A study of Carthamus tinctorius with 15 samples.

How the data were processed

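The measurements were RNA-seq expression values of safflower (Carthamus tinctorius), an oil crop of the daisy family. Values of root, stem, leaf and flower were used, with 3 libraries of each tissue and 12 libraries in all. The 3 seed libraries, whose titles carry the stage 6d, were not analysed here. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was assessed on a Bioanalyzer, and libraries were made with the VAHTS Universal V6 RNA-seq kit. The labels give each library's tissue and a replicate number. They do not say that the 3 libraries of a tissue came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

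The values deposited by the authors are FPKM, which divide the reads of a gene by its length and by the total of the library. The submitters' processing notes name fastp, HISAT2, HTSeq and R 3.2.0, without a role or an order. The genome build, the gene annotation and the strand setting are not given in the sources used here. The table has 33242 gene rows and 12 columns of values, and every column was matched to a library by its name, which is the library's title. The table used does not pair its rows with gene identifiers or names. A gene is therefore named below by its place in the table, counted from 1 at the first row of values (row 20605 is that numbered row), with the length recovered from its values. Gene names, functions and positions in the genome are not used here, and the gene lists on oil formation and other processes that had been set in advance were not analysed.

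FPKM is relative to the total of a library, so a few very abundant genes lower the values of all others. How reads shared by near-identical genes were counted is not given in the sources used here, and the level of a gene with such a copy is uncertain. Of the rows above 0, 96 were identical to another row in all 12 libraries, in 46 sets, and none of these exceeded 0.58 FPKM.

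Sequencing depth was recovered from the values. Where whole reads are counted, a gene's FPKM values are whole multiples of what 1 read is worth. Ratios of low values gave the relative totals of the libraries, and lengths in whole bases then gave the totals themselves. The gene length taken was the smallest whole number of bases that turned a row into whole reads in every library, within 0.01 reads. Of 33242 rows, 6617 were 0 in all libraries and 26625 were not, and whole reads were recovered for 100% of the latter. The recovered reads summed to between 99.99% and 100% of the library totals, which ran from 26183138 to 31500664. A read in this count may be a pair of reads. The length of a row with few reads can come out too short, and its reads too few. The column sums of FPKM ran from 770371 to 796195.

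Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, which kept 20769 genes and removed 12473 rows. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a mean for each tissue and a mean-variance trend, over all 12 libraries with 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each pair of tissues. A gene was called different between tissues at an adjusted p under 0.05 and a difference of at least 1. Enriched genes were higher in a tissue than in each of the other 3, and depleted genes lower, at an adjusted p under 0.05 and a difference of at least 2 in every pair. Genes shared by 2 tissues were higher in both of them than in both others, at the same thresholds. Differences on the log2(FPKM + 1) scale understate the change of low genes. The seed comparisons of the design were not run, and the fit was planned over 15 libraries.

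The tests, thresholds, filter, rule for naming genes and most alternatives were set before the data were examined. The named genes of each comparison are the 2 that rose most and the 2 that fell most among called genes whose libraries did not overlap between the tissues. For enriched and depleted genes, the smallest of the differences ranked them. Depleted genes of root, stem, leaf and flower, shared genes, genes read in 1 tissue alone, the share of reads in the 100 highest genes and the exact tests of each tissue against the other 9 libraries were chosen after the values were seen.

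The number of genes detected and the share of FPKM in the 100 highest genes were compared between each tissue and the other 9 libraries with a two-sided exact permutation test over 220 splits, whose smallest p is 0.0091, adjusted over 8 tests. P-values at other detection minimums, for the 500 highest genes and for shares of reads are not adjusted. Such a test treats the other 9 libraries as exchangeable, which 3 tissues are not. A tissue whose 3 libraries all lie above or all below the other 9 gets the smallest p, whatever the gap. Since libraries of a tissue were alike, the test mostly gives the rank of a tissue and not the size of its difference. Tissue specificity was measured with tau, which runs from 0 for equal levels to 1 for a single tissue, on tissue means of log2(FPKM + 1). The alternatives tried were a pseudocount of 0.1, no filter, the same total in every library, scaling by the median ratio to the geometric mean, the replicate number as a block, thresholds of 0.5 for pairs and 1 for sets of genes, only the 6 libraries compared, each library left out, and limma's voom on the recovered reads. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

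The calling step was tested on counts simulated from the mean of the 12 libraries with a dispersion of 0.01, with 200 of 20769 genes changed in flower and read in flower against leaf. It called 96% of genes raised 4-fold, 86% of genes lowered 4-fold, 86% of genes raised 2.5-fold and 68% of genes lowered 2.5-fold, with 0 false calls. These rates need not hold for the data, where 55.7% of genes differed between leaf and flower. A simulated spread of 10% gave 1.59 times the counting noise in genes of few reads, where the libraries showed 3.79 on average without flower replicate 1.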

Results

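Expression was compared between root, stem, leaf and flower of safflower, a thistle-like oil crop grown for its seeds and florets. Each tissue had 3 libraries, named here by tissue and replicate number. Library totals recovered from the values were 27813826, 26183138 and 29184532 reads in root, 28391416, 28942014 and 30563169 in stem, 30929338, 31500664 and 31413298 in leaf, and 30431421, 29363997 and 30488919 in flower. The title of the series concerns oil formation in seeds, and the seed libraries were not analysed here. The design implies 6 comparisons between the 4 other tissues. Genes are given by their row in the table and their recovered length.

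Libraries of a tissue were closest to each other. Spearman correlations across 20769 genes, which are not independent replicates, averaged 0.992 within root, 0.993 within stem, 0.992 within leaf and 0.985 within flower. Stem was near to both leaf (mean 0.852 over 9 library pairs) and root (0.832). Root and leaf were further apart (0.653), and flower stood far from stem (0.57), leaf (0.54) and root (0.525). The first principal component held 60.1% of the variance and parted flower from the other tissues. The second held 30.8% and ordered root, stem and leaf, and the third held 7.0% and parted stem from root and leaf. All 12 libraries were used, and every replicate pair differed by more than counting noise. That does not show that they came from separate plants or RNA, since several reads per molecule also exceed it.

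**Figure D1:**
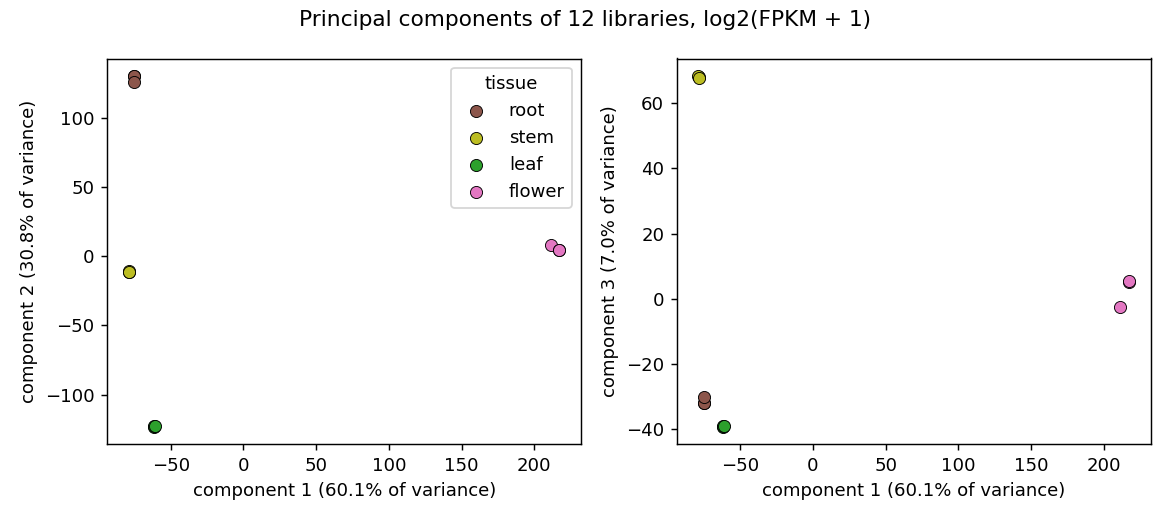
Principal components of log2(FPKM + 1) over 20769 genes, with component 1 on the horizontal axes, component 2 on the left vertical axis and component 3 on the right one. Each of the 12 points is a library, coloured by tissue, and flower lies apart on component 1 (60.1% of variance) while root, stem and leaf spread over component 2 (30.8%).

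Fewer genes were detected in flower than in the other tissues. At 1 FPKM or more, 16268 ± 177 genes (SD, n = 3) were detected in flower, 18415 ± 53.4 in root, 18496 ± 14.2 in stem and 18566 ± 12.4 in leaf. Flower was lower than the other 9 libraries (exact permutation p = 0.0091, the smallest possible; adjusted p = 0.0243) and lower in 3 of 3 libraries. Leaf was higher by the same exact test (p = 0.0091, adjusted p = 0.0243). Its rank as highest alone gives this p, and stem, at 18496 genes, was close to leaf. The 3 leaf libraries also had the most reads, from 30929338 up, against 30563169 in the next, so depth may add to the leaf result. Root (exact p = 0.7636) and stem (exact p = 0.3455) did not pass this test, and tissues that lie between others cannot reach its smallest p. At 5 FPKM the order of leaf and stem turned. Stem, with 14486 genes, was then higher than the other 9 libraries (exact permutation p = 0.0091), and leaf, with 14324, was not (exact p = 0.7455). Above 0.1 FPKM flower was still lowest, with 20259 genes against a mean of 21453 in the other 9 libraries. A fixed FPKM minimum depends on the scaling. Median-ratio factors were lowest in flower (0.715 to 0.758), and genes detected were not counted after that scaling.

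Expression was more concentrated in flower and leaf than in stem and root by their means, with 1 gene over 2% of all FPKM in flower and 1 in leaf. The 100 highest genes held 25.6% ± 1.59 (SD, n = 3) of FPKM in flower, 23.97% ± 0.143 in leaf, 16.81% ± 0.12 in stem and 15.99% ± 0.0969 in root. Root was lower than the other 9 libraries (exact permutation p = 0.0091, adjusted p = 0.0243). Its rank as lowest alone gives this p. Stem was close to root and also below leaf and flower, so the test does not set root apart from stem. The higher share in flower (exact p = 0.0364) did not pass adjustment (adjusted p = 0.0728), and leaf (exact p = 0.1545) and stem (exact p = 0.1818) did not pass the test. The order of leaf and flower depended on the measure. By reads, without division by gene length, the 100 highest genes held 22.4% in leaf (exact permutation p = 0.0091) and 20.88% in flower (exact p = 0.1818). The 500 highest genes held 46.76% of FPKM in flower (exact permutation p = 0.0091) and 42.3% in leaf (exact p = 0.3455). The genes named in this paragraph were picked after their values were seen. In flower, row 2361 (828 bases) had the highest mean, 18480 ± 1180 FPKM (SD, n = 3), which was 2.338% of the total, against 472.9 ± 8.37 in leaf. In leaf, row 29089 (1057 bases) reached 16770 ± 256 FPKM, 2.131% of the total, against 2001 ± 18.8 in stem and 14.18 ± 13.6 in root (6.308 without root replicate 3). In root and stem the highest gene was row 26099 (158 bases), with 5714 ± 593 FPKM in root, 8524 ± 1390 in stem, 4636 ± 582 in leaf and 6405 ± 244 in flower.

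**Figure D2:**
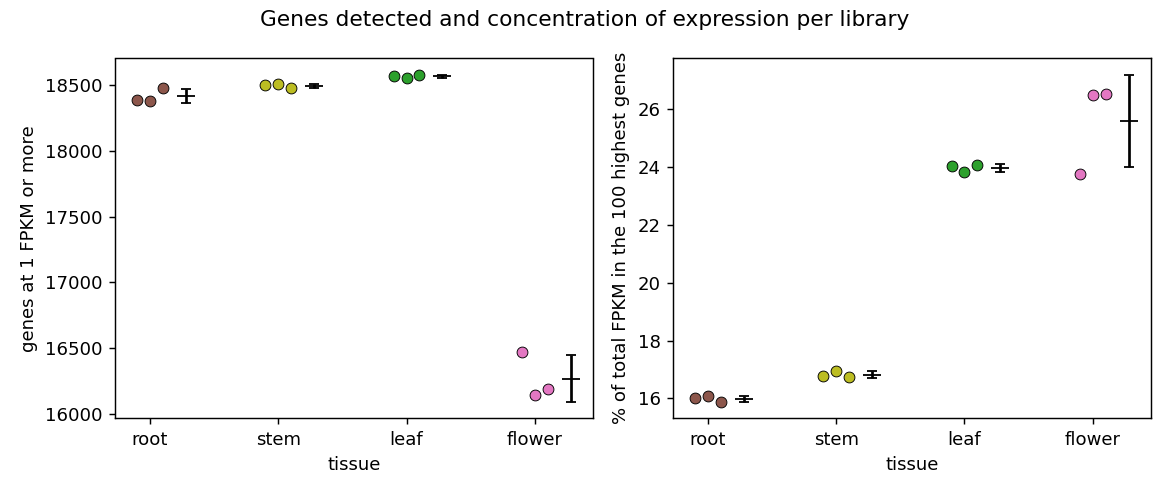
Genes at 1 FPKM or more (left) and the percent of total FPKM in the 100 highest genes (right) by tissue. Each point is a library, and the bar beside each group is the mean with its SD (n = 3). Neither vertical axis starts at 0, and flower is lowest on the left at 16268 genes while root and stem are lowest on the right at 15.99% and 16.81%.

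Root and stem were the closest pair in the number of genes that differed. Of 20769 genes, 4134 (19.9%) differed by limma, 1854 higher in root and 2280 higher in stem. The strongest in root were row 25636 (1026 bases) at 512.7 ± 15.2 FPKM (SD, n = 3) in root and 0.1117 ± 0.0528 in stem, and row 30611 (978 bases) at 263.2 ± 2.76 and 0.1866 ± 0.114 (0.1209 without stem replicate 2). Row 25636 differed by 8.85 on the log2(FPKM + 1) scale (SE 0.086, limma adjusted p = 3.24e-14) and row 30611 by 7.8 (SE 0.092). The strongest in stem were row 30133 (295 bases), at 1012 ± 6.07 FPKM in stem and 1.568 ± 2.06 in root, and row 18689 (1114 bases), at 2177 ± 29 in stem and 4.774 ± 4.07 in root. Both were still higher in leaf, at 4265 ± 23.4 FPKM for row 30133 and 4051 ± 23.8 for row 18689. Their root means rest on root replicate 3, and without it they were 0.377 FPKM for row 30133 and 2.47 for row 18689.

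Root and leaf differed in 7703 genes (37.1%). By limma 4274 of them were higher in root and 3429 in leaf, so 55.5% of the calls were higher in root. Row 13633 (303 bases) was at 804.4 ± 10.9 FPKM (SD, n = 3) in root, 30.34 ± 5.17 in stem and 0.1055 ± 0.00104 in leaf, where its 3 libraries held 3 reads in all. Row 5243 (695 bases) was at 397 ± 11.5 FPKM in root and 0.1373 ± 0.137 in leaf (0.06852 without leaf replicate 3), a difference of 8.46 on the log2(FPKM + 1) scale (SE 0.109, limma adjusted p = 3.04e-14). On the leaf side, row 20605 (842 bases) was at 14490 ± 102 FPKM in leaf and 8.045 ± 9.74 in root. Its root mean rests on root replicate 3, at 19.29 FPKM, and was 2.423 without it. Row 30133 was at 4265 FPKM in leaf, with a difference of -10.98 for root minus leaf (SE 0.372, limma adjusted p = 7.78e-11).

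Stem and leaf differed in 5242 genes (25.2%), with 2884 higher in stem and 2358 higher in leaf by limma. Row 2078 (1287 bases) was at 239.8 ± 2.69 FPKM (SD, n = 3) in stem and 0.7376 ± 0.143 in leaf, a difference of 7.12 (SE 0.34, limma adjusted p = 4.18e-09). Row 7347 (606 bases) was at 264.9 ± 4.12 in stem and 1.53 ± 0.24 in leaf. Higher in leaf were row 93 (2426 bases), at 1053 ± 7.41 FPKM in leaf and 2.029 ± 0.11 in stem, and row 28435 (1314 bases), at 684.7 ± 12 in leaf and 1.182 ± 0.262 in stem. For stem minus leaf, row 93 differed by -8.44 (SE 0.261, limma adjusted p = 1.18e-10).

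Flower differed from each other tissue in over 55% of the genes tested. Against root, 11867 genes (57.1%) differed by limma, 8273 higher in root and 3594 higher in flower. Row 20891 (776 bases) was at 1299 ± 27.6 FPKM (SD, n = 3) in root and 0.1845 ± 0.248 in flower, and row 2131 (1135 bases) at 1066 ± 8.78 and 0.3195 ± 0.451. Row 5267 (312 bases) was at 5803 ± 1100 FPKM in flower and 0.8948 ± 1.03 in root, and row 5270 (288 bases) at 5874 ± 1660 in flower and 1.551 ± 2.57 in root. Without flower replicate 1 the flower means were 0.04389 for row 20891 and 0.05946 for row 2131, and without root replicate 3 the root means were 0.2989 for row 5267 and 0.06631 for row 5270. Root minus flower was 10.12 for row 20891 (SE 0.114, limma adjusted p = 6.4e-15) and -11.69 for row 5267 (SE 0.374, limma adjusted p = 2.69e-11).

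Against stem, 11479 genes (55.3%) differed, 8090 higher in stem and 3389 higher in flower by limma. Row 1672 (801 bases) was at 728.1 ± 10.5 FPKM (SD, n = 3) in stem and 0.3827 ± 0.39 in flower, and row 5433 (244 bases) at 833.3 ± 15.4 and 1.122 ± 1.94. The flower mean of row 1672 was 0.1843 without flower replicate 1, and all flower reads of row 5433 came from that library, at 3.367 FPKM. Row 5270 and row 25608 (327 bases) were the strongest in flower, both with a stem minus flower difference of -11.14 (SE 0.53 and 0.324). Row 25608 was at 5117 ± 1160 FPKM in flower and 1.294 ± 0.711 in stem.

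Against leaf, 11561 genes (55.7%) differed, 7707 higher in leaf and 3854 higher in flower by limma. Row 20605 differed by 12.15 on the log2(FPKM + 1) scale for leaf minus flower (SE 0.91, limma adjusted p = 8.51e-08). Its flower values were 17.05 FPKM in replicate 1 and 0.364 and 0.3116 in replicates 2 and 3. Row 5433 was at 2678 ± 75.9 FPKM (SD, n = 3) in leaf and, from flower replicate 1 alone, 1.122 ± 1.94 in flower. Rows 5267 and 25608 were again the strongest in flower, with differences of -11.25 and -11.09 for leaf minus flower (SE 0.374 and 0.324).

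The balance of higher and lower calls depended on the scaling. The median gene was 0.61 lower in flower than in root on the log2(FPKM + 1) scale, 0.58 lower than in stem and 0.48 lower than in leaf, and 0.28 lower in leaf than in root. Scaling by the median ratio, with factors from 0.715 to 0.758 in flower and 1.233 to 1.252 in root, brought the root and flower median difference to 0.013 and the root and leaf one to 0.044. Relative to that shift, the share of calls higher in root went from 69.7% to 51.4% against flower and from 55.5% to 44.1% against leaf, which turned the majority to leaf. The share higher in stem went from 70.5% to 53.1% against flower and from 55% to 43.4% against leaf, which also turned the majority. The share higher in leaf against flower went from 66.7% to 54.5%, and the share higher in root against stem from 44.8% to 41.4%. Median-ratio scaling brings median differences near 0 by construction, since it takes the median gene as unchanged. Without it, 55.3% to 57.1% of genes were called in the pairs with flower. Which scaling is right was not tested. The 24 values of named genes in the pairs of tissues kept their direction and stayed called under all alternatives run. They had been picked as the strongest calls, at 6.72 or more in size against a threshold of 1. Their stability therefore says little about other genes.

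**Figure D3:**
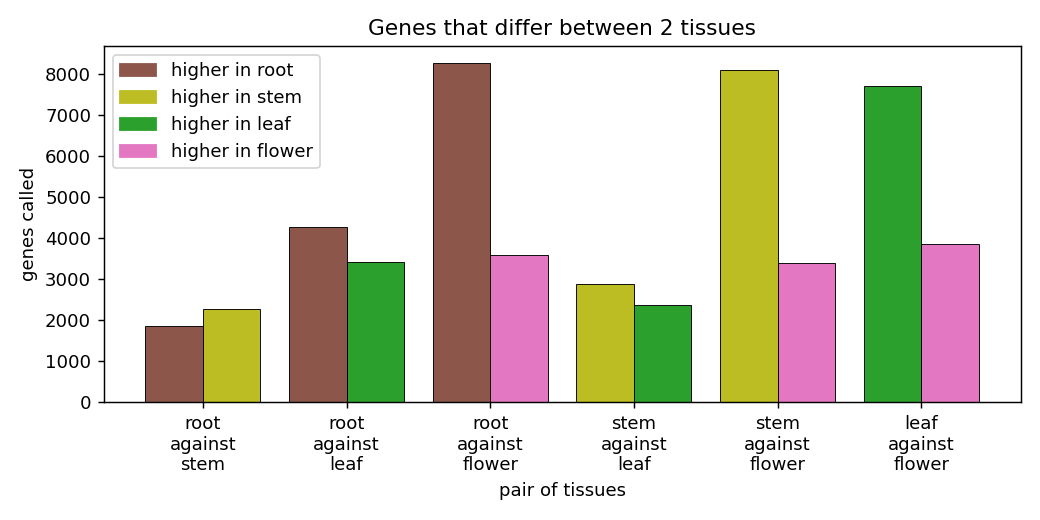
Genes called different in each of the 6 pairs of tissues (vertical axis, number of genes), with 1 bar for the genes higher in each tissue, coloured by that tissue. Root with stem gave the fewest calls (4134) and the pairs with flower gave 11479 to 11867, and with median-ratio scaling the taller bar changes side in root against leaf and in stem against leaf.

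Flower had the most genes of its own. By limma 1156 genes were higher in flower than in each of the other tissues, 493 were so in leaf, 314 in root and 58 in stem. In 20 simulations of unchanged libraries no set held a gene. With a median SE of 0.11 in each pair and a threshold of 2 that was all but certain, so it lends the sets no support. Independent lists would share 15.8 genes for flower, 12.3 for leaf, 8.4 for root and 6.8 for stem. The comparisons behind a set share libraries, and part of the excess may come from that. Row 28466 (903 bases) was at 5925 ± 968 FPKM (SD, n = 3) in flower and at most 2.119 ± 1.17 in another tissue, and row 25608 was the other leading gene of flower. Rows 93 and 28435 led the leaf genes, with smallest differences of 8.44 and 8.3, and rows 30611 and 25636 the root genes, with 7.8 and 7.37. Rows 2078 and 27979 (1778 bases) led the stem genes, with 5.42 and 4.57. Row 27979 was at 408.5 ± 4.49 FPKM in stem, 16.29 ± 0.664 in leaf, 0.3657 ± 0.239 in root (0.2306 without root replicate 3) and 0.06161 ± 0.107 in flower, where only replicate 1 had reads.

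Genes low in a single tissue were most numerous in flower, where 2028 were lower than in each other tissue by limma. Root had 381 such genes, leaf 127 and stem 9, against 151.9, 9.2, 4.5 and 1.8 for independent lists of flower, root, leaf and stem. Here too the comparisons share libraries, and part of the excess may come from that. A pseudocount of 0.1 raised the counts to 3798 in flower, 659 in root, 256 in leaf and 54 in stem. With median-ratio scaling the order of higher and lower genes in flower turned, to 1706 higher and 1388 lower. Rows 8070 (1545 bases) and 30756 (929 bases) were the lowest in flower by this measure. Row 8070 was at 0.3132 ± 0.412 FPKM (SD, n = 3) in flower (0.07633 without flower replicate 1) and 594.1 ± 3.39 in stem, and row 30756 at 1.777 ± 0.461 in flower and 644.1 ± 4.22 in leaf. In root, row 13236 (1316 bases) was at 0.6104 ± 0.96 FPKM against 488.6 ± 4.23 in stem, and row 25609 (836 bases) at 3.501 ± 3.84 against 9607 ± 1420 in flower. Without root replicate 3 these root means were 0.05634 for row 13236 and 1.297 for row 25609. In leaf, row 30652 (802 bases) was at 0.6917 ± 0.222 FPKM against 166.2 ± 5.59 in root, and row 156 (330 bases) had 2 reads over the 3 leaf libraries and 129.2 ± 5.75 FPKM in flower. In stem, row 11123 (492 bases) was at 2.51 ± 0.742 FPKM against 23.54 ± 3.15 in root, and row 31094 (1540 bases) at 0.1725 ± 0.117 against 13.65 ± 1.07. In flower these 2 genes differed between replicates, with means of 31.83 FPKM for row 11123 and 20.37 for row 31094 that were 18.75 and 8.938 without replicate 1.

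Stem shared the most genes with leaf and with root. By limma 394 genes were higher in stem and leaf than in both root and flower, and 299 were higher in root and stem than in both others, against 3.5 and 1.9 for independent lists. These comparisons share libraries, and stem is near to both leaf and root, so independent lists are too low a baseline. Root and flower shared 124 genes, leaf and flower 102, stem and flower 15, and root and leaf 10. With a pseudocount of 0.1 these 4 counts rose to 271, 196, 35 and 51, which turned the order of the last 2. Of the 7703 genes that differed between root and leaf, 79.1% (6090) had a stem mean between those of root and leaf. In the other groups of 3 tissues that share was 23.6% to 63.2%.

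**Figure D4:**
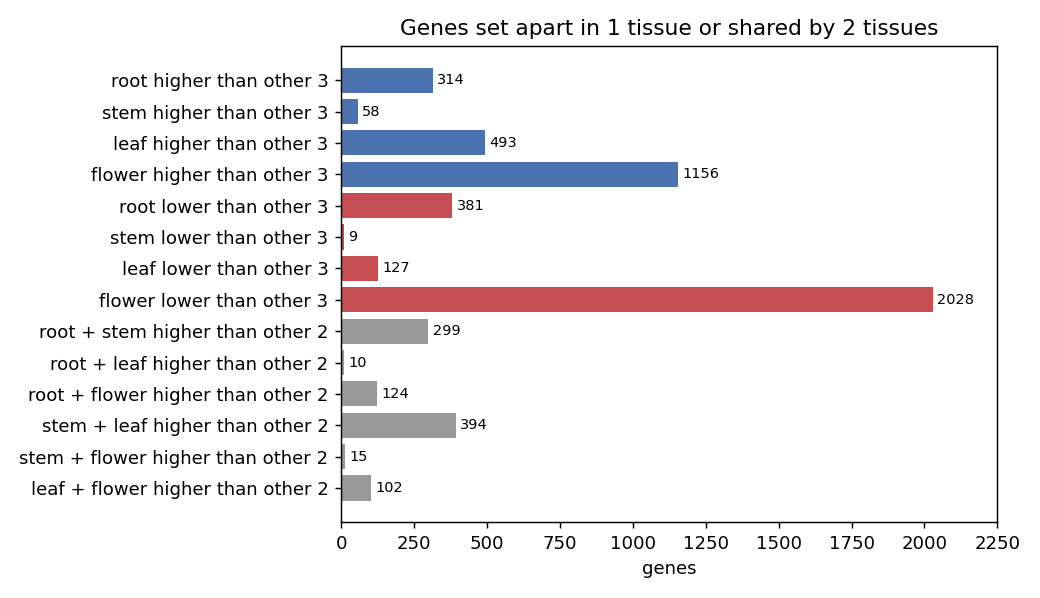
Number of genes (horizontal axis) higher in 1 tissue than in the other 3 (blue), lower in 1 tissue than in the other 3 (red) and higher in 2 tissues than in the other 2 (grey). Flower has 1156 higher and 2028 lower genes, an order that turns with median-ratio scaling, and stem has 58 and 9.

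Few genes were specific by the tau index, whose median over 20769 genes was 0.277. With tau of at least 0.8, 717 genes had their highest mean in flower, 386 in root, 360 in leaf and 51 in stem. These counts had no test. Among genes with a highest mean of at least 5 FPKM the order of root and leaf turned, to 185 in root and 217 in leaf, with 20 in stem. Reads in a single tissue alone, at 10 or more in each of its 3 libraries and 0 in the other 9, were found for 123 genes in flower, 47 in root, 14 in leaf and 1 in stem. Their median level was 2.098 FPKM in flower and 1.268 in root, so these were genes of low expression. The rule of 0 reads elsewhere favours such genes. Row 28466, at 5925 FPKM in flower, still had 108 reads in root, 167 in stem and 166 in leaf, and was left out.

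Replicates differed by several times the counting noise. The variance of the difference between replicates was 3.64 to 3.95 times the Poisson variance in 10 of the 12 replicate pairs, by the median over genes. Both pairs with flower replicate 1 were at 12.87 and 12.97. Across classes of genes from 30 to 10000 reads the mean of the 10 pairs ran from 3.72 to 5.45, with single pairs from 3.85 to 8.84 in the highest class, and in the pairs with flower replicate 1 it rose from 6.0 to 411.24. Flower replicate 1 had 427 genes at least 1 higher on the log2(FPKM + 1) scale than the mean of replicates 2 and 3, and 109 at least 1 lower. In the other 11 libraries these numbers ran from 42 to 107 and from 54 to 148. Among 136 tissue means of 34 genes, the named ones and the 3 most abundant of each tissue, leaving out flower replicate 1 moved 13 by over 1.5 times, leaving out root replicate 3 moved 14, and each other library moved 2 or fewer. Without flower replicate 1, 1148 genes were enriched and 2124 depleted in flower, and 11948, 11567 and 11629 genes differed from root, stem and leaf.

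**Figure D5:**
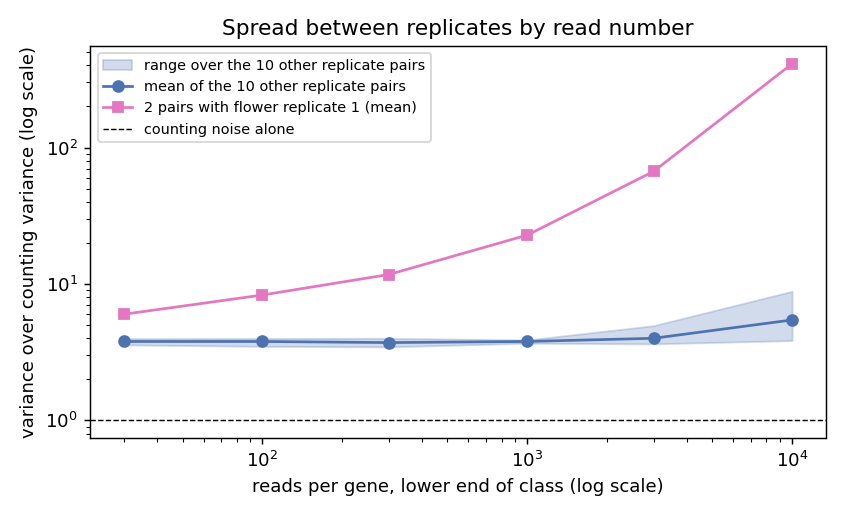
Variance of the difference between replicates over the counting variance (vertical axis, log scale) for classes of genes by read number (horizontal axis, lower end of the class, log scale). Blue points and band are the mean and range over 10 replicate pairs, from 3.72 to 5.45 on average, pink squares are the mean of the 2 pairs with flower replicate 1, reaching 411.24, and the dashed line at 1 is counting noise.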

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

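The voom fit, the share of reads, the read minimums for genes read in 1 tissue alone, all alternatives for depleted and shared genes, and the leaving out of libraries for genes detected, for the share in the 100 highest genes and for genes read in 1 tissue alone were chosen only after the results were seen. The counts of genes per pair, of enriched, depleted and shared genes stayed within 1.5 times their value without the filter, with the same total in every library and in the fits of 6 libraries (pairs only). Leaving out any 1 library also kept them there, as for the number of genes detected, the share in the 100 highest genes and the genes read in 1 tissue alone. All 24 named values kept their direction and their call in all 336 alternative values, which their choice as the strongest calls made all but certain. What follows gives the values that moved by more, whose cause was not tested except where the setting itself lowers or raises a bar.

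A pseudocount of 0.1 raised the enriched genes to 533 in root and 104 in stem, and the depleted genes to 659 in root, 54 in stem, 256 in leaf and 3798 in flower. Shared genes became 481 for root and stem, 51 for root and leaf, 271 for root and flower, 626 for stem and leaf, 35 for stem and flower and 196 for leaf and flower. The voom fit gave like values, with 555 and 111 enriched in root and stem, and 757, 76, 325 and 4178 depleted in root, stem, leaf and flower. Its shared genes were 552 for root and stem, 68 for root and leaf, 309 for root and flower, 692 for stem and leaf, 55 for stem and flower and 230 for leaf and flower. By construction, both settings shrink the differences of low genes less. With tau, the pseudocount of 0.1 left 199 genes in root, 14 in stem, 185 in leaf and 431 in flower, and a highest mean of at least 5 FPKM left 185 in root, 20 in stem and 217 in leaf.

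Median-ratio scaling raised the genes higher in flower to 5469 against root and 5168 against stem, and those shared by leaf and flower to 157. Thresholds of 0.5 for pairs and 1 for sets gave 7919 genes between root and stem (4048 higher in root, 3871 in stem), 12810 between root and leaf (8082 higher in root) and 10128 between stem and leaf (6039 higher in stem, 4089 in leaf). Enriched genes became 1049 in root, 317 in stem, 1556 in leaf and 2265 in flower, and depleted genes 856, 87, 637 and 5193. Shared genes became 1235 for root and stem, 84 for root and leaf, 434 for root and flower, 945 for stem and leaf, 104 for stem and flower and 405 for leaf and flower.

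A detection minimum of 0.1 FPKM gave 21472 genes in root, 21377 in stem, 21510 in leaf and 20259 in flower, and 5 FPKM gave 14358, 14486, 14324 and 11638. The 10 highest genes held 4.12%, 4.47%, 8.02% and 9.09% of FPKM in root, stem, leaf and flower, and the 500 highest 35.1%, 35.8%, 42.3% and 46.8%. The 100 genes with most reads held 14.5%, 15.2%, 22.4% and 20.9% of the recovered reads. At a minimum of 3 reads, 99, 2, 31 and 200 genes were read in root, stem, leaf and flower alone, and at 30 reads 23, 0, 5 and 67. These settings measure other quantities by construction. Pearson in place of Spearman correlation moved 6 of 10 means by more than their spread, the most for root and leaf (0.626 against 0.653). Depth limits the genes read in 1 tissue alone, since a gene at 0 reads can hold a low level.

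With the replicate number as a replicate block, 4134 genes differed between root and stem, 7702 between root and leaf and 11866 between root and flower, and 313 were enriched in root. Deviations of libraries with the same number correlated from -0.04 to 0.03, none of 18 above 0.1, and 6 of 12 libraries were closest to libraries of their own number. The alternatives for seed, for the gene lists and for leaving out seed libraries were not run, since no seed value or gene name was used.

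Every one of the 6 pairs of tissues has 10 splits of its 6 libraries, too few for a share under 0.05. The true split was 1 of 10 with as many calls in each pair, and the highest other split called 1 gene in stem against leaf and 0 in the other pairs. Among 100 groupings of the 12 libraries, as many enriched genes as observed came from 4 groupings for root (314 observed, highest other 1369), 2 for stem (58, highest other 1351), 2 for leaf (493, highest other 558) and 1 for flower (1156, highest other 0). Each share was under 0.05, without adjustment over the sets. Each of those other groupings kept 3 libraries of a tissue together, and groupings that kept no 3 together gave 0 genes. The test therefore shows only that libraries of a tissue are alike. It cannot exclude chance differences between plants or pools of RNA, since the libraries of a tissue may be technical.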

Other observations

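The tests of reads carried between libraries were chosen only after example values had been seen, and the other tests were set before their results were seen. Genes next to each other in the table had more similar tissue profiles than random pairs. The mean correlation over the 4 tissue means was 0.18 for 12228 adjacent pairs and 0.083 for random pairs, and it fell to 0.125 at 2 rows and 0.108 at 3 rows apart. Without adjacent pairs of lengths within 10% the excess over random pairs was 0.095. This argues against near-identical copies of like length as the whole cause. Copies that differ more in length were kept, so they are not excluded. At 100 rows apart 4.6% of the excess was left, which argues against rows sorted by a trait over the whole table. A hypothesis is that the table follows the order of genes on chromosomes and that neighbours may be expressed alike, which needs gene positions that were not used here. Among the most abundant flower genes, row 5267 lies near row 5270, and row 25608 next to row 25609. These examples were picked after their values were seen. The profiles of the second pair differed outside flower. Row 25609 was at 1066 FPKM in stem and 966.4 in leaf, where row 25608 was at 1.294 and 1.305. Stem exceeded both leaf and root in 450 genes, and was below both in 185, so a mix of leaf and root RNA, which cannot exceed both of its parts, is not the whole of the stem profile.

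Flower replicate 1 stood apart from flower replicates 2 and 3. Its variance ratio against replicate 2 was 3.33 times that between replicates 2 and 3, which argues against the sampling of reads as the cause. The best-fitting mix of other tissues added 0.499% of root, 0.019% of stem and 0.12% of leaf, and brought 13 of 536 deviating genes (2.4%) within 0.5, which argues against RNA of those tissues as the main cause. Of the 20 most abundant flower-enriched genes, 2 were higher in replicate 1 than in the mean of the others, and of all 1156 such genes 503 were (median difference -0.09). Of the genes enriched in other tissues, 163 of 314 for root, 30 of 58 for stem and 266 of 493 for leaf were higher (median differences 0.02, 0.01 and 0.02), and 15, 13 and 15 of the top 20 of each. Another stage or part of the flower, or another plant, may explain this, and none of these was tested, since the labels give no stage of the flowers.

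Replicates other than flower replicate 1 differed by a multiple of counting noise that rose little with read number on average, though in the highest class it ran from 3.85 to 8.84. The mean multiple in the class of most reads was 1.44 times that in the class of fewest. Single pairs had an SD of 0.41 and a range of 1.03 to 2.47. Most of the 10 library pairs share libraries, so this SD is not the error of the 1.44. Simulated replicates with 4 reads per molecule gave 4.04 and 3.95 in the lowest and highest classes, and simulated plants with a spread of 10% gave 1.59 and 192.08. At 1.44 the ratio lies near the bound of 1.5 set for it, and the range of single pairs reaches to both sides of that bound. The ratio alone therefore cannot tell a fixed number of reads per molecule, such as duplicates, from a small spread between plants. In the class of fewest reads, however, the 10 pairs were at 3.58 to 3.98, above the simulated 1.59. In the highest class their mean of 5.45 was far below the simulated 192.08. For these pairs, this argues against a spread of like percent in every gene as the whole cause. A small spread on top of several reads per molecule stays open. Libraries made from 1 pool of RNA per tissue may look like this too, and the labels do not say how plants were pooled.

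Some abundant genes of leaf were higher in root replicate 3 and flower replicate 1 than in the other replicates of those tissues. Over leaf-enriched genes of at least 100 FPKM in leaf and, in the other replicates, under 0.2% of the leaf level, the median excess was 0.0847% of the leaf level in root replicate 3 (quartiles 0.044% and 0.1174%, 60 of 69 genes higher) and 0.0759% in flower replicate 1 (quartiles 0.0361% and 0.1161%, 47 of 54 higher). Without the second limit it was 0.0737% (quartiles -0.028% and 0.1525%, 116 of 166 higher) and 0.0521% (quartiles -0.2305% and 0.2227%, 100 of 166 higher), since genes that these tissues express spread by more than such a share. With the same limits, flower-enriched genes were higher in root replicate 3 (0.0426%, quartiles 0.0181% and 0.0788%, 90 of 105 genes) and stem replicate 1 (0.0202%, 64 of 86), and root-enriched genes in flower replicate 1 (0.0309%, 16 of 23). A candidate explanation is that a like share of all leaf RNA or reads was carried into these libraries, but the quartiles over all leaf-enriched genes are too wide to tell, and it stays open for both.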
